A study of Mus musculus with 12 samples.

How the data were processed

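RNA sequencing of inguinal white adipose tissue from 12 mice was analysed, with 3 libraries in each of the groups WT_30C, AKO_30C, WT_8C and AKO_8C, taken from the sample labels. Per the submitters' processing notes, reads were converted with bcl2fastq, checked with FastQC 0.11.3, aligned to build mm10 with TopHat2 2.0.14 and quantified with Cufflinks 2.2.1, and the annotation and options were not stated. The deposited gene table, although named a gene count, holds FPKM, which the authors made, since 99.986% of its nonzero values are not whole numbers, its columns have different sums, and the mean of a group's 3 columns equals the FPKM in the authors' comparison tables. That match was exact to rounding for all 2150 group values of the 8 °C table and all 1748 that could be matched in the 30 °C table, where 2 genes were not in the gene table. The authors' comparison tables give FPKM per group, a log2 fold change of AKO over WT, a test statistic (a score), a p-value and a q-value, per the file headers. The p-value and q-value are the authors' own, and so is the log2 fold change, which carries no pseudocount. The tables hold no read counts, so the depth per library is unknown and no counting error is given.

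Genes were tested when they reached 1 FPKM in at least 3 libraries, which kept 13215 of 24344. Scd1 and Snora81 were left out because they were listed at 0 in some libraries and at 1000 FPKM or more in others, a limit set after a lower one was seen to remove Cyp2b10. A further 25 gene symbols, 20 of them tested, had been turned into dates in the table and are not named. Values were taken as log2(FPKM + 1) with the authors' scaling between libraries. Each comparison was tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 libraries, a variance trend, no other covariate, two-sided tests, and a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. The comparisons were AKO against WT at 30 °C and at 8 °C, 8 °C against 30 °C in WT and in AKO, and the interaction, which is the AKO over WT difference at 8 °C minus that at 30 °C. Tests for read counts could not be applied to FPKM, and limma had been set as the fallback. Figures used Python 3.11.15. On simulated data with the same spread, the test recovered 32 of 67 genes changed 1.5-fold, 62 of 67 changed 2-fold and 65 of 66 changed 4-fold at 30 °C, and 33, 59 and 64 at 8 °C, while calling 11 and 7 of 12990 unchanged genes.

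Before the data were examined, the groups, comparisons, 33 gene lists, cell type markers, alternative analyses and the rule for named genes were fixed. The lists were the thermogenic programme, nuclear and mitochondrially encoded OXPHOS subunits, the tricarboxylic acid cycle, fatty acid oxidation, de novo lipogenesis, triglyceride storage and lipolysis, calcium and creatine cycling, glycolysis, XBP1s targets, ATF6 targets and chaperones, ATF4 and the integrated stress response, transcripts reported to be cleaved by IRE1 (RIDD), collagen and matrix, inflammatory cytokines, interferon response, cell cycle, immediate early genes, heat shock and the circadian clock. Marker lists were adipocyte, macrophage, T cell, B cell, neutrophil and mast cell, skeletal muscle, epithelium, endothelium, fibroblast and adipose progenitor, smooth muscle and pericyte, Schwann cell, erythrocyte and sex-linked genes. The 30 lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data and with the rotation test fry. In simulated data with independent genes, camera called a list of 25 genes shifted by 0.5 and 0 of 30 other lists. Named genes were Ern1 and Xbp1, then, in each comparison, up to 12 called genes in each direction with the largest fold change, a mean of at least 1 FPKM (the rule was written for scaled counts and used here for FPKM) and no overlap of the groups (not asked of the interaction), predicted genes left out. They also included up to 4 members of a list with the smallest adjusted p or any member where its list is described, 15 genes of thermogenesis, stress and adipocyte function, and the 5 highest and 5 lowest of each authors' table. Results that name items withheld for evaluation were left out. Positions are those of the GRCm38 annotation.

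Alternatives set in advance, and adapted here to FPKM where they had been written for counts, were no filter on low values, the 6 libraries of a comparison alone, a replicate block, each library left out in turn, a robust variance estimate, a minimum absolute log2 fold change of 1, the list tests above, an adjusted p of 0.10 for the overlap, and authors' genes with a mean of at least 1 FPKM. Added after the values were seen were pseudocounts of 0.1 and 0.5, a filter at 5 FPKM, no variance trend, and scaling of the libraries by median ratio, upper quartile or to an equal sum. Splits of the samples into other groups were counted for each test, over all 10 splits of 3 against 3 or over 100 drawn for the interaction. Gene families chosen after their values were seen were tested with Fisher's exact test. Checks of the libraries showed a highest correlation of 0.989 between 2 libraries, a lowest within a group of 0.978 and no identical columns. Reads were not used, so exon deletion in Ern1 and splicing of Xbp1 were not analysed.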

Results

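Total RNA from inguinal white adipose tissue, the subcutaneous fat pad of the mouse groin, was sequenced from 12 mice of the C57BL/6J strain. The mice spent 4 weeks at room temperature and 6 weeks at 30 °C, where a mouse needs little extra heat production, and were then held at 8 °C or 30 °C for 3 more days. The 4 groups of 3 mice were WT_30C, AKO_30C, WT_8C and AKO_8C, where WT and AKO are the genotypes as the labels give them and the series title names a floxed Ern1 line. Expression was given as FPKM (fragments scaled to transcript length and library size) for 24344 genes in each library. The number of reads behind each value is therefore unknown. Between 12433 and 12818 genes reached 1 FPKM in a library, and the FPKM of a library summed to between 594202 and 743185. The first principal component held 66.1% of the variance of the 13215 genes tested and separated 8 °C from 30 °C. Fold changes below are log2 differences of group means of FPKM plus 1, which shrinks the change of genes near 1 FPKM, and values are means ± SD (n = 3). For each gene named below for a large fold change between 2 groups, the 3 libraries of one group lay above the 3 of the other.

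Ern1 encodes IRE1, the endoplasmic reticulum sensor that splices Xbp1 mRNA when unfolded proteins accumulate, and lies on chromosome 11, 106394650 to 106487852 (GRCm38). Its level was 2.94 ± 0.395 FPKM in WT_30C and 4.06 ± 0.544 FPKM in AKO_30C, and 4.96 ± 0.375 FPKM in WT_8C and 7.04 ± 0.288 FPKM in AKO_8C. Ern1 was thus not lower in the libraries labelled AKO at either temperature, and all 3 AKO values exceeded all 3 WT values at both. The AKO values at 30 °C were 4.50, 4.24 and 3.45 against 2.53, 3.32 and 2.97 FPKM in WT, and at 8 °C they were 6.83, 6.92 and 7.37 against 4.53, 5.16 and 5.20 FPKM. The log2 fold change of AKO over WT was 0.36 at 30 °C (SE 0.12, adjusted p = 0.193) and 0.43 at 8 °C (SE 0.12, adjusted p = 0.0756), so neither passed the test. Cold raised Ern1 by 0.60 in WT (adjusted p = 0.00131) and by 0.67 in AKO (adjusted p = 0.000547). A gene-level FPKM sums all exons, so it cannot show whether some exons were deleted. Nor can it exclude that the labels WT and AKO were exchanged, which would turn the sign of each AKO over WT difference below, where the genotype is given as the labels state it. Xbp1, the transcription factor of this pathway on chromosome 11, 5520659 to 5525893 (GRCm38), had 96.7 ± 6.999 FPKM in WT_30C, 114 ± 28.7 FPKM in AKO_30C, 78.5 ± 10.6 FPKM in WT_8C and 107 ± 40.3 FPKM in AKO_8C. It passed the test in no comparison, with adjusted p between 0.340 in WT between the temperatures and 0.847 for the interaction, and its spliced form cannot be told from the unspliced one in these values.

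The comparison of AKO with WT at 30 °C asks what the genotype changed in fat at rest. At 30 °C, genes of fibroblasts, extracellular matrix, resident macrophages and mast cells lay higher in the libraries labelled AKO. With an estimated correlation these list calls were lost (adjusted p = 0.181, 0.181, 0.181 and 0.195). Pi16, a marker of interstitial fibroblast progenitors on chromosome 17, 29317680 to 29330593 (GRCm38), rose from 4.89 ± 0.866 FPKM to 105 ± 56.3 FPKM, a log2 fold change of 4.05 (SE 0.58, adjusted p = 0.0292). Of 13215 genes tested, 100 were higher and 5 lower in AKO, 1909 having an unadjusted p under 0.05. The other stromal genes among the 12 largest increases were Pcolce2, an enhancer of procollagen processing, Igfbp6, which binds insulin-like growth factors, Cd248, a stromal surface glycoprotein, Sfrp2, a secreted modulator of Wnt signalling, Lrrn4cl and Fndc1, with log2 fold changes of 3.06 for Pcolce2, 2.87 for Igfbp6, 2.49 for Cd248, 2.36 for Sfrp2, 2.34 for Lrrn4cl and 2.32 for Fndc1. Macrophage genes among them were Fcna, a ficolin, Retnla, made by alternatively activated macrophages, Cd209f, a lectin receptor, and Folr2, a folate receptor of resident macrophages, at 2.96 for Fcna, 2.80 for Retnla, 2.78 for Cd209f and 2.27 for Folr2. The remaining one was Mrgprg, a Mas-related receptor, at 2.51. The 5 genes that fell were Gh, growth hormone, at -1.05, Lcn4, a lipocalin, at -0.94, Hcn3, an ion channel subunit, at -0.77, Gadd45b, a stress-induced gene, at -0.70, and H2-K2, a class I histocompatibility gene, at -0.64. Gh lies on chromosome 11, 106300271 to 106301865 (GRCm38), close to Ern1.

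**Figure D1:**
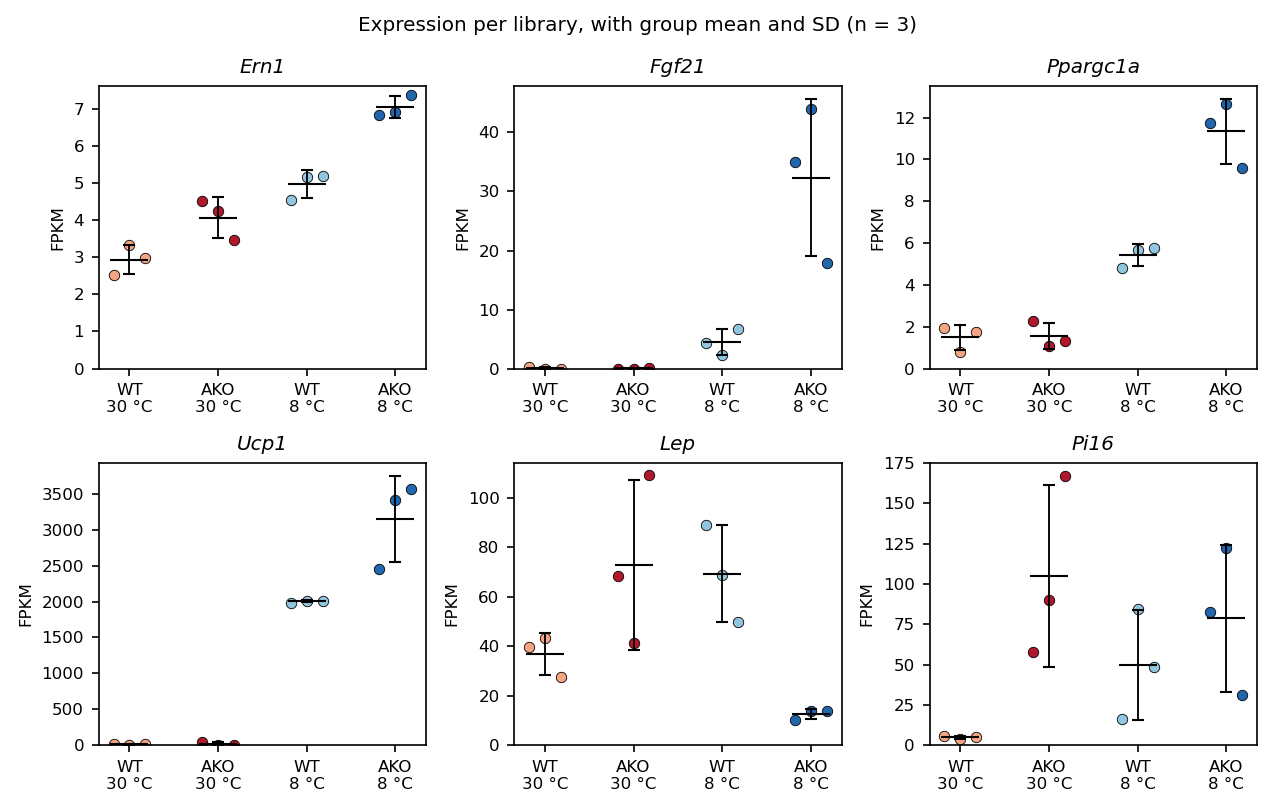
FPKM of Ern1, Fgf21, Ppargc1a, Ucp1, Lep and Pi16 in each of the 12 libraries by group, with points for libraries and bars for the mean and SD of 3. Ern1 was 3.45 FPKM or more in the AKO_30C libraries and 3.32 FPKM or less in the WT_30C libraries, and Pi16 had a mean of 105 FPKM in AKO_30C against 4.89 FPKM in WT_30C.

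Of 12 fibroblast and adipose progenitor genes, 3 rose over all genes tested and 10 adjusted over the list alone, with a median log2 fold change of 1.14 (camera adjusted p = 3.39e-12, or 0.181 with an estimated correlation). Cd34, a progenitor surface marker, rose by 1.47 and Dcn, the collagen-binding proteoglycan decorin, by 1.28. The matrix list had 2 of 20 higher, Mmp2, a matrix protease, by 1.58 and Loxl1, a collagen and elastin crosslinking enzyme, by 1.51, and 15 adjusted over the list alone, at a median of 0.71 (camera adjusted p = 2.13e-13, or 0.181 with an estimated correlation). Among 16 macrophage markers, 2 rose, the complement gene C1qc by 1.25 and the mannose receptor Mrc1 by 1.46, and 11 adjusted over the list alone, at a median of 0.86 (camera adjusted p = 4.09e-12, or 0.181 with an estimated correlation). The neutrophil and mast cell list had 3 of 10 higher and 5 adjusted over the list alone, all 3 being mast cell proteases, Tpsb2 at 2.24, Mcpt4 at 2.15 and Cma1 at 2.04, with a median of 1.41 (camera adjusted p = 9.97e-06, or 0.195 with an estimated correlation). In the endothelium list 1 of 12 rose, the angiopoietin receptor Tek by 0.88, and 1 adjusted over the list alone, at a median of 0.28 (camera adjusted p = 3.61e-06, or 0.181 with an estimated correlation). None of 9 smooth muscle and pericyte genes passed limma's test, 3 being higher at an unadjusted p under 0.05, and the list's median was 0.36 (camera adjusted p = 0.00150, or 0.181 with an estimated correlation). Of 11 transcripts reported to be cleaved by IRE1, 0 passed limma's test over all genes, 5 were higher at an unadjusted p under 0.05, and 4 rose adjusted over the list alone, namely Scara3, Sparc, Hgsnat and Col6a1, at a median of 0.17 (camera adjusted p = 0.000399, or 0.181 with an estimated correlation). Sparc and Col6a1 are also products of fibroblasts, but a stromal source of the rise was not tested.

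T cell markers lay lower in AKO at 30 °C, with a list median of -0.49, 0 of 14 past limma's test over all genes, 11 lower at an unadjusted p under 0.05 and 10 adjusted over the list alone (camera adjusted p = 3.21e-08, or 0.274 with an estimated correlation). B cell markers had a median of -0.34 with 0 of 14 past the test and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0201, or 0.917 with an estimated correlation). Cell cycle genes had a median of -0.26 with 0 of 18 past it and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.00715, or 0.867 with an estimated correlation). Adipocyte markers had a median of 0.15 with 0 of 16 past limma's test and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.00825, or 0.7996 with an estimated correlation). Fatty acid oxidation genes lay at 0.12 with 0 of 22 past the test and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0203, or 0.917 with an estimated correlation). Triglyceride storage genes lay at 0.14 with 0 of 20 past it and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0195, or 0.867 with an estimated correlation). Calcium and creatine cycling genes lay at 0.25 with 0 of 9 past the test and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0331, or 0.342 with an estimated correlation). The calcium and creatine call was made under 3 of 4 scalings. With 1 library left out, the B cell call was lost at an adjusted p of 0.0737 without WT_30C replicate 1, 0.0534 without WT_30C replicate 3 and 0.339 without AKO_30C replicate 1, in a range of 0.00136 to 0.339. The cell cycle call was lost at 0.0534 without WT_30C replicate 3, in a range of 0.000320 to 0.0534. The adipocyte call was lost at 0.227 without WT_30C replicate 3, in a range of 0.00110 to 0.227. The fatty acid oxidation call was lost at 0.364 without WT_30C replicate 3 and 0.435 without AKO_30C replicate 1, in a range of 9.47e-06 to 0.435. For triglyceride storage it was lost at 0.753 without WT_30C replicate 3 and 0.107 without AKO_30C replicate 1, in a range of 0.000437 to 0.753, and for calcium and creatine cycling at 0.325 without WT_30C replicate 1 and 0.0935 without AKO_30C replicate 3, in a range of 0.00372 to 0.325.

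The thermogenic programme (0.213), glycolysis (0.294), de novo lipogenesis (0.163), immediate early (0.497), heat shock (0.519), circadian clock (0.0775), epithelium (0.946), Schwann cell (0.327) and inflammatory (0.405) lists did not pass at 30 °C, where each value is camera's adjusted p. In the inflammatory list the chemokine Ccl8 rose by 1.42 over all genes and the cytokine Tnf was lower adjusted over the list alone, at -0.78. Among lists of the thermogenic and stress programmes, limma called 0 of 29 thermogenic genes, 0 of 37 XBP1s targets, 0 of 16 ATF6 targets and 0 of 23 ATF4 targets, with 3 higher and 1 lower, 1 higher and 1 lower, 0, and 1 higher and 2 lower at an unadjusted p under 0.05. The nuclear OXPHOS list had a median of -0.00185 and an upward test (0.589), and its median was positive under the 3 other scalings. It passed as lower without AKO_30C replicate 1, at an adjusted p of 0.00132, and as higher without AKO_30C replicate 3, at 0.00215. The tricarboxylic acid cycle list had a median of 0.01, a mean of -0.02 and an upward test (0.765). XBP1s targets had a median of -0.02, ATF6 targets -0.03, ATF4 targets -0.02 and interferon genes -0.02. Each had an upward test (0.966) and a median above 0 under 2 of the other scalings. Skeletal muscle genes had a median of -0.06, a mean of 0.16 and an upward test (0.445). Other lists passed with 1 library left out, by adjusted p. Without WT_30C replicate 1 they were Schwann cell at 0.0367 (lower). Without WT_30C replicate 3 they were lipogenesis at 9.99e-06, glycolysis at 0.0302, muscle at 0.00372 and Schwann cell at 0.00639 (higher). Without AKO_30C replicate 1 they were tricarboxylic acid cycle at 0.000921 (lower), lipogenesis at 0.00820, glycolysis at 0.0386 and muscle at 0.0461. Without AKO_30C replicate 2 they were circadian at 0.0140. Without AKO_30C replicate 3 they were thermogenic at 0.00227 and tricarboxylic acid cycle at 0.0263 (higher). Too few erythrocyte and sex-linked genes were measured for the list test, 4 each, with none past limma's test and 0 and 2 lower at an unadjusted p under 0.05, and the gene table held none of the mitochondrially encoded subunits.

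Ucp1 had a log2 fold change of 0.24 (adjusted p = 0.880), Lep of 0.88 (adjusted p = 0.228) and Dnajb9 of -0.21 (adjusted p = 0.559), and none of the 15 genes named in advance passed the test at 30 °C. The same holds for Ppargc1a, Cidea, Dio2, Elovl3, Prdm16, Hspa5, Sec61a1, Bloc1s1, Ddit3, Adipoq, Fasn and Adrb3. Groups did not overlap for 2530 genes, 19.1% of those tested, where chance gives 10% for 3 against 3. With no filter on low values, limma called 1 gene (2326 at an unadjusted p under 0.05) and 0 of the 17 genes named for their fold change. Single libraries also moved the count. limma called 0 genes without WT_30C replicate 1, 2 or 3 or AKO_30C replicate 1 (1183, 2736, 1324 and 1682 at an unadjusted p under 0.05), 29 without AKO_30C replicate 2 and 2 without AKO_30C replicate 3. Of the 17 genes, 4 were still called without AKO_30C replicate 2 and 0 in the other 5 fits.

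**Figure D2:**
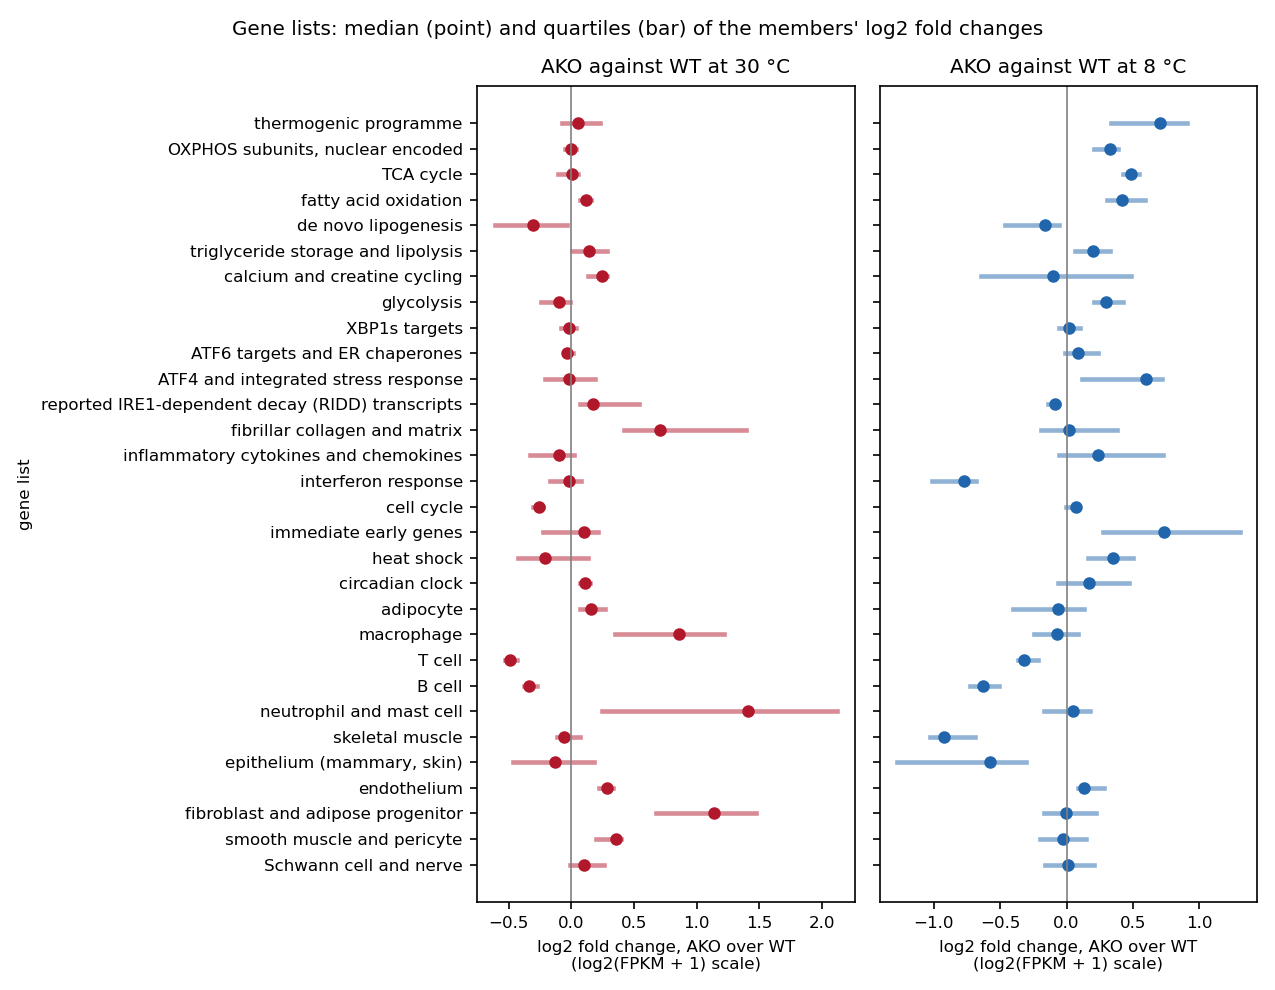
Log2 fold change of AKO over WT for the 30 gene lists tested, at 30 °C in red and at 8 °C in blue, with the median of the members as a point and the quartiles as a bar. The fibroblast list had a median of 1.14 at 30 °C and -0.00381 at 8 °C, and the thermogenic list 0.05 and 0.70.

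The comparison of AKO with WT at 8 °C asks what the genotype changed in fat under cold. After 3 days at 8 °C, genes of the integrated stress response lay higher in the libraries labelled AKO, and Lep and the macrophage genes Cd5l and Marco were lower. Genes of heat production and fuel oxidation lay higher as lists, calls lost with an estimated correlation (adjusted p = 0.538 for thermogenic genes, 0.538 for fatty acid oxidation and 0.542 for OXPHOS subunits). Fgf21, a metabolic hormone of fat and liver on chromosome 7, 45613886 to 45615490 (GRCm38), rose from 4.46 ± 2.22 FPKM to 32.3 ± 13.3 FPKM, a log2 fold change of 2.60 (SE 0.32, adjusted p = 0.00472). Lep, which encodes the satiety hormone leptin on chromosome 6, 29060220 to 29073877 (GRCm38), fell from 69.2 ± 19.6 FPKM to 12.5 ± 2.05 FPKM, a log2 fold change of -2.35 (SE 0.31, adjusted p = 0.00577). Of 13215 genes tested, 193 were higher and 75 lower in AKO. Scaling changed this split to 155 higher and 102 lower after upper quartile scaling and to 85 higher and 93 lower after scaling each library to the same sum. The other genes among the 12 largest increases were Trib3, a pseudokinase, Chac1, which degrades glutathione, and Gdf15, a stress cytokine, all known targets of the integrated stress response, at 1.63 for Trib3, 1.31 for Chac1 and 1.54 for Gdf15. They also held Acot2, a mitochondrial acyl-CoA thioesterase, Itga5, the fibronectin receptor subunit, Tnfrsf12a, the TWEAK receptor, Emp1, a membrane protein, and Mrgprg, at 1.53 for Acot2, 1.55 for Itga5, 1.36 for Tnfrsf12a, 1.48 for Emp1 and 1.80 for Mrgprg. The last of them were Glod5, Zfp949, a zinc finger gene, and Morf4l1-ps1, a pseudogene, at 1.82 for Glod5, 1.88 for Zfp949 and 1.85 for Morf4l1-ps1. Ptx3, an acute phase pentraxin, was also called at 3.19 (adjusted p = 0.0451), but its libraries overlapped, and it is named here after its values were seen. Largest among the decreases were Saa3, an acute phase protein, Rmrp, an RNA of the RNase MRP complex, Cd5l, a protein secreted by macrophages, and Marco, a macrophage scavenger receptor, at -3.51 for Saa3, -2.40 for Rmrp, -2.13 for Cd5l and -1.94 for Marco. The others were Cdsn, Slfn8, Igfals, a carrier of insulin-like growth factors, Stc2, Chst12, Mid1ip1, an activator of fatty acid synthesis, and Lst1, at -1.40 for Cdsn, -1.28 for Slfn8, -1.21 for Igfals, -1.19 for Stc2, -1.11 for Chst12, -1.10 for Mid1ip1 and -1.09 for Lst1.

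Of 23 genes of ATF4 and the integrated stress response, 7 rose over all genes tested and 12 adjusted over the list alone, with a median log2 fold change of 0.60 (camera adjusted p = 5.68e-07, or 0.0118 with an estimated correlation). Besides Trib3, Chac1 and Ddit3, they included Atf4 itself at 0.71, Atf5 at 0.67, Mthfd2, an enzyme of mitochondrial folate metabolism, at 0.91 and Vldlr, a lipoprotein receptor, at 0.96. Among 37 XBP1s targets 1 rose over all genes and 2 adjusted over the list alone, and the list did not pass (adjusted p = 0.913), its median being 0.02 and below 0 under the 3 other scalings. The XBP1s target Dnajb9, an endoplasmic reticulum co-chaperone, rose by 0.70 (adjusted p = 0.0430). In the ATF6 and chaperone list 2 of 16 rose, Hspa5, the main chaperone of the endoplasmic reticulum, by 0.46 (adjusted p = 0.0319) and Herpud1 by 0.69, and the list did not pass (adjusted p = 0.228). Ddit3, the transcription factor CHOP, rose by 0.68 (adjusted p = 0.0483), while Sec61a1 (0.02, adjusted p = 0.944) and Bloc1s1 (-0.11, adjusted p = 0.601) did not pass. Immediate early genes had a median of 0.74 with 0 of 16 past limma's test and 3 higher at an unadjusted p under 0.05 (camera adjusted p = 0.0118, or 0.748 with an estimated correlation). Heat shock genes had a median of 0.35 with 0 of 12 past it and 3 higher at an unadjusted p under 0.05 (camera adjusted p = 0.0225, or 0.685 with an estimated correlation). The immediate early call was lost at an adjusted p of 0.542 without WT_8C replicate 1, 0.310 without WT_8C replicate 3 and 0.134 without AKO_8C replicate 2, in a range of 6.02e-22 to 0.542, and the heat shock call at 0.219 without WT_8C replicate 1 and 0.177 without AKO_8C replicate 2, in a range of 0.00284 to 0.219.

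The thermogenic programme had 6 of 29 genes higher over all genes tested and 14 adjusted over the list alone, with a median of 0.70 (camera adjusted p = 8.1e-09, or 0.538 with an estimated correlation). The 6 were Fgf21, Dio2, which activates thyroid hormone, at 1.06, Gyk, glycerol kinase, at 0.99, Ppargc1a, the coactivator of mitochondrial genes, at 0.94, Letmd1 at 0.72 and Zfp516 at 0.49. Ucp1, the uncoupling protein of brown and beige fat, had 2001 ± 13.8 FPKM in WT_8C and 3148 ± 602 FPKM in AKO_8C, and its log2 fold change of 0.63 (SE 0.57, adjusted p = 0.588) did not pass. Nor did Cidea (0.70, adjusted p = 0.306), Elovl3 (0.64, adjusted p = 0.105), Prdm16 (0.06, adjusted p = 0.902) or Adrb3 (-0.37, adjusted p = 0.332). Nuclear OXPHOS subunits lay higher as a list, at a median of 0.33 with 0 of 76 past limma's test over all genes, 54 higher at an unadjusted p under 0.05 and 46 adjusted over the list alone (camera adjusted p = 1.22e-15, or 0.542 with an estimated correlation). The tricarboxylic acid cycle list lay at 0.49 with 0 of 18 past the test, 14 higher at an unadjusted p under 0.05 and 13 adjusted over the list alone (camera adjusted p = 2.99e-07, or 0.542 with an estimated correlation). For fatty acid oxidation 2 of 22 rose, Acot2 and the carnitine palmitoyltransferase Cpt1a at 0.48, and 13 adjusted over the list alone, at a median of 0.42 (camera adjusted p = 8.73e-10, or 0.538 with an estimated correlation). For glycolysis 2 of 16 rose, Pfkp at 0.48 and Pgk1 at 0.51, and 4 adjusted over the list alone, at a median of 0.29 (camera adjusted p = 0.000180, or 0.538 with an estimated correlation). De novo lipogenesis had 2 of 18 lower, Scd2, a stearoyl-CoA desaturase, at -1.02 and Srebf1, a regulator of lipid synthesis, at -0.82, and 3 adjusted over the list alone, at a median of -0.16 (camera adjusted p = 0.0105, or 0.703 with an estimated correlation). That call was lost at an adjusted p of 0.0699 without AKO_8C replicate 3, in a range of 0.000345 to 0.0699. In the calcium and creatine cycling list, which did not pass (adjusted p = 0.531), Ckb, a creatine kinase, rose by 0.77 and Atp2a2, a calcium pump, by 0.49, while the median was -0.10 and the test upward, and 4 rose and 1 fell adjusted over the list alone.

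Interferon response genes were lower in AKO at 8 °C, 2 of 20 over all genes tested and 16 adjusted over the list alone, at a median of -0.78 (camera adjusted p = 2.19e-13, or 0.538 with an estimated correlation). The RNA sensor Ddx58, at -0.69, was among those past the test. Markers of other cell types moved in the same direction. B cell markers had a median of -0.63 with 0 of 14 past limma's test, 8 lower at an unadjusted p under 0.05 and 1 adjusted over the list alone (camera adjusted p = 2.99e-07, or 0.542 with an estimated correlation). T cell markers lay at -0.32 with 0 of 14 past it and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 6.26e-05, or 0.548 with an estimated correlation). Skeletal muscle markers lay at -0.93 with 0 of 16 past it and 5 lower at an unadjusted p under 0.05 (camera adjusted p = 7.34e-06, or 0.548 with an estimated correlation). The macrophage list had 1 of 16 lower, Aif1 at -0.61, with 1 higher and 2 lower adjusted over the list alone, and did not pass (adjusted p = 0.166). Adipocyte markers did not pass (adjusted p = 0.166), with Lep the one member lower, Adipoq at -0.50 (adjusted p = 0.137) and Fasn of the lipogenesis list at -0.15 (adjusted p = 0.895). In the circadian list, at an adjusted p of 0.166, the repressor Nfil3 rose by 1.20, and 4 genes rose adjusted over the list alone. The inflammatory list (0.606) had 1 gene lower, the RIDD list (0.228) 1 higher. Triglyceride storage (0.166), cell cycle (0.913), epithelium (0.0623), endothelium (0.155) and smooth muscle (0.606) did not pass, each value being camera's adjusted p. The stromal lists that stood out at 30 °C did not pass at 8 °C, the fibroblast list with a median of -0.00381, a mean of 0.01 and an adjusted p of 0.606. The matrix list had a median of 0.02, below 0 under the 3 other scalings, and an adjusted p of 0.834. Neutrophil and mast cell genes had a median of 0.05, below 0 under 2 other scalings, with a downward test (0.723). Schwann cell genes had a median of 0.01, with the opposite sign under the 3 other scalings (0.834). Other lists passed with 1 library left out, by adjusted p. Without WT_8C replicate 1 they were triglyceride at 0.00478 and macrophage at 0.000509. Without WT_8C replicate 2 they were inflammatory at 0.00740, adipocyte at 0.0264, epithelium at 0.0112 and endothelium at 0.0340. Without WT_8C replicate 3 they were circadian at 0.0278, adipocyte at 0.0231 and epithelium at 0.00415. Without AKO_8C replicate 1 they were cell cycle at 0.0470 and endothelium at 0.0155. Without AKO_8C replicate 2 they were macrophage at 0.0138 and fibroblast at 0.0269.

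At 8 °C the groups did not overlap for 3191 genes, 24.1% of those tested, where chance gives 10% on average, and 2560 genes had an unadjusted p under 0.05. With 1 library left out, limma called 85, 122 and 45 genes without WT_8C replicates 1, 2 and 3 and 196, 147 and 23 without AKO_8C replicates 1, 2 and 3. A fit of the 6 libraries at 8 °C alone called 6 genes, with 2423 at an unadjusted p under 0.05. Of 29 called genes that the naming rule took for their fold change or in advance, 14, 16 and 8 were called without WT_8C replicates 1, 2 and 3, and 15, 17 and 10 without AKO_8C replicates 1, 2 and 3. Acot2 and Lep were called in all 17 alternatives, Acot2 at adjusted p of 0.00107 to 0.0291.

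The comparison of 8 °C with 30 °C in WT gives the cold response of control fat. In WT, genes of heat production, mitochondrial respiration and fuel oxidation were higher after 3 days of cold, and those of skeletal muscle, lymphocytes and cell division lower. Muscle and B cell markers also varied together between libraries of one group, at mean correlations of 0.749 and 0.901. Ucp1, on chromosome 8, 83290352 to 83298452 (GRCm38), rose from 9.28 ± 3.89 FPKM to 2001 ± 13.8 FPKM, a log2 fold change of 7.69 (SE 0.57, adjusted p = 3.11e-06). Of 13215 genes tested, 3211 rose and 3268 fell, and after scaling each library to the same sum, which shifted the median of all genes to -0.14, 2446 rose and 4512 fell. The other large increases were Elovl3, which elongates fatty acids, Fabp3, a fatty acid binding protein, Slc25a34, a mitochondrial carrier, Gyk, Phospho1, a phosphatase, Pla2g2e, a phospholipase, Kng2, a kininogen, and Dio2, at 6.96 for Elovl3, 5.24 for Fabp3, 4.43 for Slc25a34, 4.19 for Gyk, 3.88 for Phospho1, 3.80 for Pla2g2e, 3.79 for Kng2 and 3.77 for Dio2. Cyp2b10, a cytochrome P450 gene, was listed at 0 in the WT_30C libraries and had 44.0 ± 43.7 FPKM in WT_8C. S100a8, a neutrophil protein, rose by 4.12, Saa3 by 3.83 and Fgf21 by 2.25 (adjusted p = 0.000162), to 4.46 ± 2.22 FPKM. Nnat, neuronatin, fell to -3.46, and most of the other large decreases were muscle genes, Casq1, Pvalb, Pgam2, Tnnc2, Tcap, Ckm, Mylpf, Myoz1 and Acta1, at -2.94 for Casq1, -2.91 for Pvalb, -2.41 for Pgam2, -2.37 for Tnnc2, -2.12 for Tcap, -2.10 for Ckm, -2.07 for Mylpf, -2.04 for Myoz1 and -2.02 for Acta1. Sap25 lay at -2.10, and Eif3j1 at -3.96, although its value is uncertain because it was near 0 in libraries where its paralog Eif3j2 was high.

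Thermogenic genes rose in 24 of 29 cases (24 adjusted over the list alone) at a median of 2.25 (camera adjusted p = 1.62e-12, or 0.366 with an estimated correlation). Among them Cidea, a lipid droplet protein, was at 2.35 and Ppargc1a at 1.39. Nuclear OXPHOS subunits rose in 74 of 76 (74 adjusted over the list alone) at a median of 1.21 (camera adjusted p = 5.38e-31, or 0.366 with an estimated correlation). Cycs, cytochrome c, reached 2.09. All 18 tricarboxylic acid cycle genes rose (18 adjusted over the list alone), at a median of 1.61 (camera adjusted p = 1.86e-10, or 0.393 with an estimated correlation). Fatty acid oxidation genes rose in 21 of 22 (21 adjusted over the list alone), at 1.63 (camera adjusted p = 9.28e-14, or 0.366 with an estimated correlation). Lipogenesis had 10 of 18 higher and 10 adjusted over the list alone, at a median of 1.09 (camera adjusted p = 0.000275, or 0.5004 with an estimated correlation). Acly, which makes acetyl-CoA from citrate, was at 1.69 and Fasn, fatty acid synthase, at 1.42. Triglyceride storage had 16 of 20 higher and 16 adjusted over the list alone (camera adjusted p = 9.28e-07, or 0.409 with an estimated correlation). Glycolysis had 13 of 16 higher and 13 adjusted over the list alone (camera adjusted p = 1.1e-05, or 0.366 with an estimated correlation). Adipocyte markers rose in 10 of 16 and in 11 adjusted over the list alone (camera adjusted p = 0.00287, or 0.513 with an estimated correlation). Adipoq rose by 0.46 and Lep by 0.88. Endothelial genes rose in 8 of 12 and in 8 adjusted over the list alone (camera adjusted p = 0.00346, or 0.439 with an estimated correlation). Flt1, a receptor of vascular growth factors, was at 0.96. Neutrophil and mast cell genes rose in 8 of 10 and in 9 adjusted over the list alone (camera adjusted p = 0.00342, or 0.457 with an estimated correlation). Of the stress genes, Dnajb9 rose by 1.22, Bloc1s1 by 0.49 and Hspa5 by 0.34, and the ATF4 list, 9 up and 4 down of 23, did not pass (adjusted p = 0.159).

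T cell markers were lower in WT at 8 °C, 14 of 14 over all genes and 14 adjusted over the list alone, at a median of -1.29 (camera adjusted p = 1.32e-08, or 0.393 with an estimated correlation). Il7r, the interleukin 7 receptor, was at -1.52. B cell markers fell in 12 of 14 and in 13 adjusted over the list alone, at -0.99 (camera adjusted p = 0.000244, or 0.513 with an estimated correlation). Skeletal muscle markers fell in 13 of 16 and in 13 adjusted over the list alone, at -1.82 (camera adjusted p = 0.000164, or 0.513 with an estimated correlation). Cell cycle genes fell in 18 of 18 and in 18 adjusted over the list alone, at -0.74 (camera adjusted p = 1.4e-05, or 0.5004 with an estimated correlation). Among lists that did not pass, the inflammatory list had a median of 0.36 and a downward test (0.640). The calcium and creatine list, which holds the muscle genes Atp2a1 and Ckmt2, had a median of 0.00129, below 0 under 2 other scalings, a mean of -0.01 and an upward test (0.565). The circadian list had a median of -0.09, a mean of 0.04 and an upward test (0.832). Other lists passed with 1 library left out, by adjusted p. Without WT_30C replicate 1 they were Schwann cell at 0.000511. Without WT_30C replicate 2 they were matrix at 0.0259. Without WT_30C replicate 3 they were heat shock at 0.0220. Without WT_8C replicate 1 they were heat shock at 0.0353, macrophage at 0.00775 and fibroblast at 0.0459. Without WT_8C replicate 3 they were matrix at 0.0262 and fibroblast at 0.0429. The matrix list also passed under 1 other scaling. The groups did not overlap for 7671 genes, 58.0% of those tested, where chance gives 10% on average, and 7417 genes had an unadjusted p under 0.05.

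**Figure D3:**
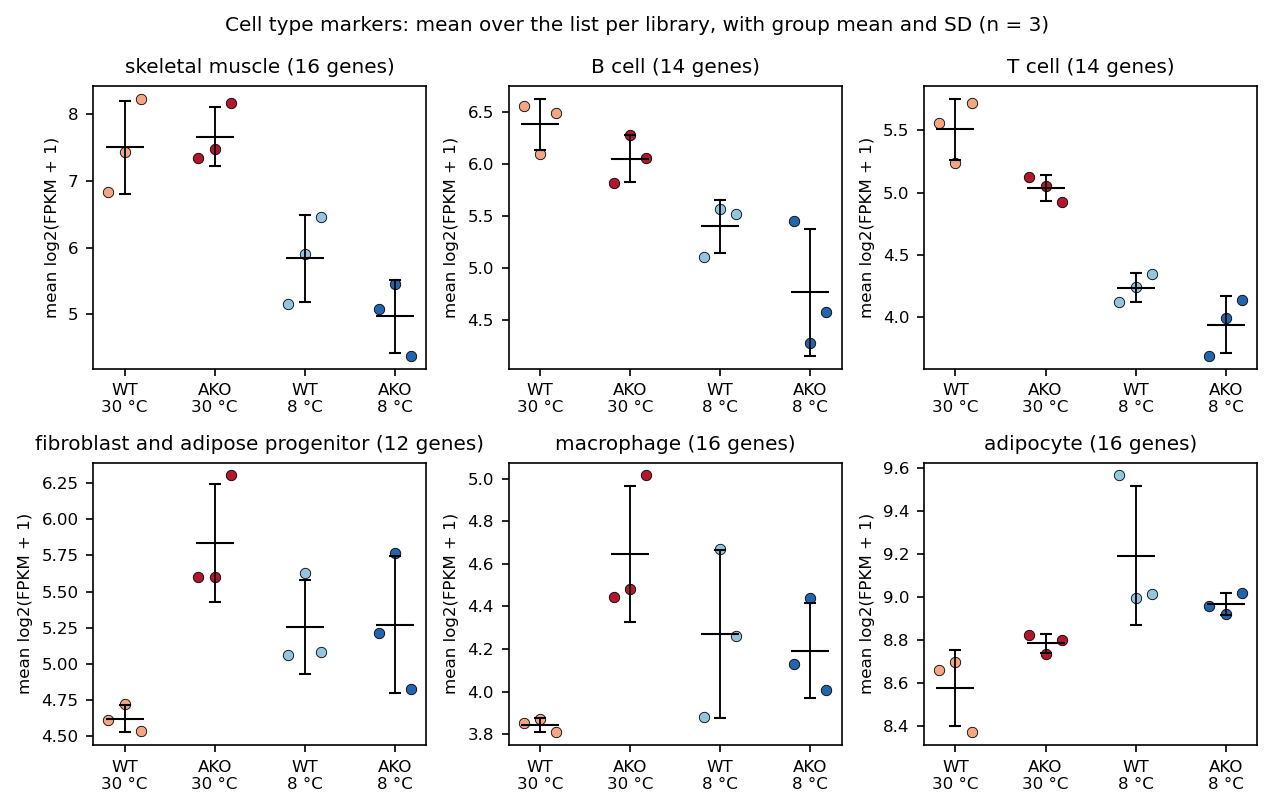
Mean log2(FPKM + 1) of the markers of 6 cell types in each of the 12 libraries by group, with points for libraries and bars for the mean and SD of 3. Muscle, B cell and T cell markers were lower at 8 °C than at 30 °C in both genotypes, and fibroblast markers were between 5.60 and 6.31 in AKO_30C against 4.53 to 4.72 in WT_30C.

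The same comparison in AKO gives its cold response. In the AKO libraries heat production, respiration and fuel oxidation genes were higher at 8 °C, and muscle and lymphocyte genes and Lep lower. Ucp1 rose from 16.2 ± 19.0 FPKM to 3148 ± 602 FPKM, a log2 fold change of 8.08 (SE 0.57, adjusted p = 6.03e-07). Fgf21 rose from 0.0257 ± 0.0445 FPKM to 32.3 ± 13.3 FPKM, at 4.93 (adjusted p = 3.62e-07), and Lep changed by -2.35 (adjusted p = 6.88e-05). Of 13215 genes tested, 3498 rose and 3050 fell, with 2985 and 4072 after upper quartile scaling and 2260 and 5302 after scaling each library to the same sum, which shifted the median of all genes to -0.23. The other large increases were Elovl3, Cyp2b10, Gyk, Fabp3, Dio2, Slc25a34, Phospho1, Pla2g2e and Kng2, at 7.67 for Elovl3, 5.74 for Cyp2b10, 5.19 for Gyk, 4.98 for Fabp3, 4.92 for Dio2, 4.80 for Slc25a34, 4.35 for Phospho1, 3.95 for Pla2g2e and 3.90 for Kng2, and Fam131c, which was listed at 0 in AKO_30C and had 22.8 ± 5.80 FPKM in AKO_8C. The large decreases were Nnat at -4.14, the muscle genes Casq1, Myh1, Pgam2, Pvalb, Acta1, Tnnc2, Ckm, Mylpf and Tcap, at -3.53 for Casq1, -3.47 for Myh1, -3.40 for Pgam2, -3.37 for Pvalb, -3.17 for Acta1, -3.15 for Tnnc2, -3.00 for Ckm, -2.99 for Mylpf and -2.97 for Tcap, and Prtn3, a neutrophil protease, at -2.92. Snord17, a small nucleolar RNA, had 23.5 ± 17.99 FPKM in AKO_30C and was listed at 0 in AKO_8C. Of the genes named in advance, Cidea at 3.07, Ppargc1a at 2.29, Dnajb9 at 2.13, Fasn at 1.88, Hspa5 at 0.84 and Ddit3 at 0.81 rose, and Adrb3, the adrenergic receptor of adipocytes, fell to -0.82.

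In AKO, 23 of 29 thermogenic genes rose and 1, Adrb3, fell, the same counts holding adjusted over the list alone, at a median of 2.95 (camera adjusted p = 8.71e-13, or 0.241 with an estimated correlation). OXPHOS subunits rose in 75 of 76 and fell in 1, Atp5g1 at -0.44, with 75 and 1 adjusted over the list alone (camera adjusted p = 1.82e-32, or 0.268 with an estimated correlation). All 18 tricarboxylic acid cycle genes rose, 18 adjusted over the list alone (camera adjusted p = 1.88e-11, or 0.336 with an estimated correlation). All 22 fatty acid oxidation genes rose too, 22 adjusted over the list alone (camera adjusted p = 2.02e-14, or 0.268 with an estimated correlation). Lipogenesis had 15 higher and 1 lower of 18, the latter Srebf1, with 15 and 1 adjusted over the list alone (camera adjusted p = 0.00249, or 0.681 with an estimated correlation). Triglyceride storage had 16 of 20 higher and 18 adjusted over the list alone (camera adjusted p = 8.23e-06, or 0.420 with an estimated correlation). Glycolysis had 14 of 16 higher, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.05e-07, or 0.247 with an estimated correlation). The ATF4 list had 15 higher and 1 lower of 23, with 15 and 1 adjusted over the list alone (camera adjusted p = 0.00105, or 0.127 with an estimated correlation). Trib3, at 2.82, and Atf5, at 2.62, were among the former. Heat shock genes rose in 9 of 12 and fell in 1, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.00462, or 0.531 with an estimated correlation). Interferon genes fell in 7 of 20, and in 7 adjusted over the list alone (camera adjusted p = 0.00124, or 0.681 with an estimated correlation). Ifit3 was at -1.38. T cell markers fell in 14 of 14, and in 14 adjusted over the list alone (camera adjusted p = 1.37e-07, or 0.372 with an estimated correlation). B cell markers fell in 14 of 14, and in 14 adjusted over the list alone (camera adjusted p = 7.9e-06, or 0.531 with an estimated correlation). Muscle markers fell in 16 of 16, and in 16 adjusted over the list alone (camera adjusted p = 1.37e-07, or 0.420 with an estimated correlation). Cell cycle genes fell in 8 of 18, and in 8 adjusted over the list alone (camera adjusted p = 0.00210, or 0.681 with an estimated correlation). Macrophage markers fell in 4 of 16, Aif1 at -1.16, and in 3 adjusted over the list alone (camera adjusted p = 0.0264, or 0.730 with an estimated correlation). The macrophage call was made under 2 of 4 scalings and lost at an adjusted p of 0.112 without AKO_30C replicate 3 and 0.0656 without AKO_8C replicate 3, in a range of 0.00459 to 0.112. Epithelial genes, which did not pass, had a median of 0.09, below 0 under 1 other scaling, and a downward test (0.972). The calcium and creatine list had a median of -0.72 and an upward test (0.972). Other lists passed with 1 library left out, by adjusted p. Without AKO_30C replicate 1 they were fibroblast at 0.0280. Without AKO_30C replicate 2 they were fibroblast at 0.0292 and Schwann cell at 0.0309. Without AKO_8C replicate 1 they were immediate early at 0.0409 and endothelium at 0.0225. Without AKO_8C replicate 2 they were matrix at 0.0308, fibroblast at 0.00459 and Schwann cell at 0.0469. Immediate early genes also passed under 2 other scalings.

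Both cold comparisons called 4753 genes, of which 2497 rose in both, 2232 fell in both and 24 went opposite ways, where independent lists would share 850 rising and 754 falling genes. Across all genes tested, which are not independent replicates, the log2 fold changes of the cold response in WT and in AKO had a Pearson correlation of 0.834 and a Spearman correlation of 0.807, and the comparisons shared no libraries. In AKO the groups did not overlap for 7750 genes, 58.6% of those tested, where chance gives 10% on average, and 7460 genes had an unadjusted p under 0.05. Scd1, the main stearoyl-CoA desaturase of fat, was listed at 0 in all 6 libraries at 8 °C and at 1200 to 3826 FPKM in the 6 at 30 °C, so it was left out of the tests and no fold change is given.

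The interaction asks whether the genotype difference itself changed between 30 °C and 8 °C. limma called 15 genes, 8 with a larger and 7 with a smaller AKO over WT difference at 8 °C, and 1965 had an unadjusted p under 0.05. Lep showed a log2 interaction of -3.23 (SE 0.44, adjusted p = 0.0267), with 36.8 ± 8.39 FPKM in WT_30C, 72.8 ± 34.3 FPKM in AKO_30C, 69.2 ± 19.6 FPKM in WT_8C and 12.5 ± 2.05 FPKM in AKO_8C. The acute phase gene Saa3, the macrophage genes Marco and Cd5l, the chemokine Ccl8, the complement component C6 and Mfsd12 also had negative values, -3.99 for Saa3, -3.51 for Marco, -2.70 for Cd5l, -2.17 for Ccl8, -1.69 for C6 and -1.12 for Mfsd12. Acot2 had the largest positive value, 1.58 (SE 0.21, adjusted p = 0.0267), followed by the kininogen gene Kng1 at 1.56, which is named after its value was seen because its mean was under 1 FPKM. The others were Hcn2, an ion channel subunit, Mreg, Perm1, a regulator of mitochondrial genes in muscle, Mrgbp, Sat1, an enzyme of polyamine breakdown, and Wars, the cytosolic tryptophanyl-tRNA synthetase, at 1.32 for Hcn2, 1.31 for Mreg, 1.20 for Perm1, 1.02 for Mrgbp, 0.98 for Sat1 and 0.68 for Wars. Fgf21 was at 2.68, Dio2 at 1.15 and Ppargc1a at 0.90 (adjusted p = 0.0544, 0.160 and 0.203). Ucp1 lay at 0.39 (adjusted p = 0.847) and Ern1 at 0.07, below 0 under upper quartile and equal-sum scaling (adjusted p = 0.865). Pi16 was at -3.33 (adjusted p = 0.146), so a difference between the temperatures was not shown for any of these. With 1 library left out, limma called 0 genes without WT_30C replicate 1 or 3, AKO_30C replicate 3 or AKO_8C replicate 1 or 3, with 1405, 1731, 1399, 1741 and 1421 at an unadjusted p under 0.05. It called 1 without WT_30C replicate 2 or AKO_30C replicate 2, and 2 without AKO_30C replicate 1, against 13, 15 and 12 without WT_8C replicates 1, 2 and 3 and 17 without AKO_8C replicate 2.

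The ATF4 and integrated stress response list had the interaction that held with an estimated correlation, at a median of 0.49 with 0 of 23 past limma's test, 12 higher and 2 lower at an unadjusted p under 0.05 and 8 adjusted over the list alone (camera adjusted p = 5.55e-05, or 0.0397 with an estimated correlation). Thermogenic genes lay at 0.57, with 9 adjusted over the list alone (camera adjusted p = 0.000134, or 0.405 with an estimated correlation). OXPHOS subunits lay at 0.32 (camera adjusted p = 1.12e-09, or 0.479 with an estimated correlation). Tricarboxylic acid cycle genes lay at 0.50 (camera adjusted p = 7.91e-05, or 0.479 with an estimated correlation). Fatty acid oxidation lay at 0.29, with Acot2 past the test and 1 adjusted over the list alone (camera adjusted p = 0.000453, or 0.530 with an estimated correlation). Glycolysis lay at 0.52, with 6 adjusted over the list alone (camera adjusted p = 0.000191, or 0.277 with an estimated correlation). Other lists had a negative interaction. Interferon genes lay at -0.79 (camera adjusted p = 5.85e-10, or 0.307 with an estimated correlation). Macrophage markers lay at -0.90, with 8 adjusted over the list alone (camera adjusted p = 5.09e-10, or 0.277 with an estimated correlation). Fibroblast markers lay at -1.15, with 10 adjusted over the list alone (camera adjusted p = 1.64e-09, or 0.277 with an estimated correlation). Matrix genes lay at -0.93, with 9 adjusted over the list alone (camera adjusted p = 5.09e-08, or 0.277 with an estimated correlation). Neutrophil and mast cell genes lay at -1.43, with 3 adjusted over the list alone (camera adjusted p = 6.4e-05, or 0.277 with an estimated correlation). RIDD transcripts lay at -0.33, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000199, or 0.277 with an estimated correlation). Muscle markers lay at -0.91 (camera adjusted p = 2.56e-05, or 0.479 with an estimated correlation). Smooth muscle genes lay at -0.39 (camera adjusted p = 0.00375, or 0.277 with an estimated correlation). Adipocyte markers lay at -0.30 with Lep past the test (camera adjusted p = 0.00237, or 0.479 with an estimated correlation). B cell markers lay at -0.30 (camera adjusted p = 0.0155, or 0.699 with an estimated correlation). Endothelial genes lay at -0.17 (camera adjusted p = 0.0241, or 0.479 with an estimated correlation). Cell cycle genes lay at 0.33 (camera adjusted p = 0.0338, or 0.717 with an estimated correlation). Heat shock genes lay at 0.45 (camera adjusted p = 0.0180, or 0.479 with an estimated correlation). These last 5 calls were lost with 1 library left out. The adipocyte call was lost at an adjusted p of 0.0515 without WT_30C replicate 3 and 0.0728 without WT_8C replicate 1, in a range of 0.000249 to 0.0728. The B cell call was lost at 0.102 without WT_30C replicate 2, 0.186 without AKO_30C replicate 2, 0.105 without WT_8C replicate 2, 0.0523 without WT_8C replicate 3, 0.361 without AKO_8C replicate 2 and 0.0945 without AKO_8C replicate 3, in a range of 1.2e-08 to 0.361. The endothelium call was lost at 0.0907 without WT_30C replicate 1, 0.0680 without WT_8C replicate 1, 0.0728 without WT_8C replicate 2 and 0.181 without AKO_8C replicate 1, in a range of 0.00342 to 0.181. The cell cycle call was lost at 0.109 without WT_30C replicate 1, 0.149 without WT_30C replicate 3, 0.124 without AKO_30C replicate 1, 0.306 without WT_8C replicate 1 and 0.632 without AKO_8C replicate 1, in a range of 0.00248 to 0.632. The heat shock call was lost at 0.0816 without WT_30C replicate 3, 0.0797 without AKO_30C replicate 2, 0.0930 without WT_8C replicate 1 and 0.135 without AKO_8C replicate 2, in a range of 0.00272 to 0.135. Medians and tests differed in sign for lists that did not pass, with positive medians and downward tests for lipogenesis (0.05), triglyceride storage (0.05), calcium and creatine cycling (0.10) and XBP1s targets (0.04), of which the first 2 flipped under 2 scalings and the last under 3. Other lists passed with 1 library left out, by adjusted p. Without WT_30C replicate 2 they were lipogenesis at 0.0222 and T cell at 0.0360. Without WT_8C replicate 2 they were inflammatory at 0.000543, immediate early at 1.41e-15 and epithelium at 0.0456. Without WT_8C replicate 3 they were epithelium at 0.0236. Without AKO_8C replicate 1 they were lipogenesis at 0.0473 and T cell at 0.0103. Without AKO_8C replicate 2 they were inflammatory at 0.0294. With all 12 in, the inflammatory list passed under 1 other scaling and immediate early genes under 2.

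The overlap of the genotype comparisons asks whether the same genes differed at both temperatures. Of 105 genes called at 30 °C and 268 at 8 °C, 3 were called in both, all in the same direction. Independent lists would share 1.46 rising and 0.0284 falling genes. Mrgprg rose by 2.51 at 30 °C and 1.80 at 8 °C, the interferon-inducible gene Ifi204 by 1.29 and 0.99, and Lcn4 was at -0.94 and -0.68. Across genes, which are not independent replicates, the log2 fold changes had Pearson and Spearman correlations of 0.162 and 0.166. The comparisons shared no libraries. At an adjusted p of 0.10, 24 genes were in both, 3 opposite and 21 in the same direction. So were 367 at an unadjusted p under 0.05 in limma, and 3 calls may understate sharing. The overlap was 0 without WT_30C replicate 1, 2 or 3, AKO_30C replicate 1, WT_8C replicate 1 or 3, or AKO_8C replicate 3. These fits had 214, 444, 227, 222, 397, 234 and 318 such genes at that p. The overlap was 8 without WT_8C replicate 2 and 1 without AKO_8C replicate 1.

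The authors' deposited tables list IRE1-regulated genes at each temperature, by a test of their own. At 8 °C their table held 549 genes higher and 526 lower in AKO, of which they marked 916 as significant, with a largest p-value of 0.04985. The smallest fold change in it was 1.5004. Among the highest log2 fold changes there were 4.31 for Cplx1, 3.98 for Ptx3, 3.72 for Csf3 and 2.86 for Fgf21, and the lowest -6.09 for Tmprss2, -6.05 for Wfdc18, -6.03 for Krt8, -5.17 for Saa3 and -4.49 for Ltf. Krt8, Wfdc18 and Tmprss2, genes of epithelium, were highest in WT_8C replicate 1, with 18.6, 45.4 and 4.51 FPKM. The other WT_8C libraries had 0.967 and 0.654, 1.56 and 2.36, and 0.275 and 0.0690 FPKM, still above all AKO_8C libraries. At 30 °C the table held 694 higher and 182 lower, of which 746 were marked. There the highest values were 5.37 for Atp1a4, 4.75 for Myh7, 4.73 for Duox1, 4.50 for Mrgprg and 4.42 for Pi16, and the lowest -2.71 for Ctse, -2.21 for Zglp1, -2.07 for Eps8l1, -2.03 for Tlr1 and -1.89 for 1600023N17Rik. Of the 8 °C genes, 981 were among those tested here and 180 (18.3%) passed limma's test, 756 having an unadjusted p under 0.05. Of the 30 °C genes, 796 were tested and 102 (12.8%) passed, 631 having an unadjusted p under 0.05. All of them had the same direction in both sources, which follows from the shared FPKM values. With 1 library left out, 68, 93 and 40 of the 8 °C genes passed without WT_8C replicates 1, 2 and 3 and 20 without AKO_8C replicate 3. Of the 30 °C genes, 28 passed without AKO_30C replicate 2, 1 without AKO_30C replicate 3 and 0 without AKO_30C replicate 1 or any WT_30C library. For these the counts of all genes at an unadjusted p under 0.05 in limma were 1682, 1183, 2736 and 1324.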

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

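The test of sample splits below was planned before the result was seen. These 15 genes are listed because the AKO over WT differences at 8 °C and 30 °C differed in limma's interaction test, and each log2 value comes with both differences.

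Of these genes, 7 had a value below 0. Lep, leptin, stood at -3.23 (SE 0.44, adjusted p = 0.0267), from 0.88 at 30 °C and -2.35 at 8 °C. For Saa3, an acute phase protein, the value was -3.99 (SE 0.61, adjusted p = 0.0336), with 0.48 at 30 °C and -3.51 at 8 °C. Marco, a macrophage scavenger receptor, had -3.51 (SE 0.47, adjusted p = 0.0267), from 1.56 at 30 °C and -1.94 at 8 °C. Cd5l, a macrophage protein, stood at -2.70 (SE 0.38, adjusted p = 0.0270), from 0.56 at 30 °C and -2.13 at 8 °C. For Ccl8, a chemokine, the value was -2.17 (SE 0.35, adjusted p = 0.0444), with 1.42 at 30 °C and -0.76 at 8 °C. C6, a complement component, had -1.69 (SE 0.28, adjusted p = 0.0444), from 1.20 at 30 °C and -0.48 at 8 °C. Mfsd12 stood at -1.12 (SE 0.17, adjusted p = 0.0336), from 0.31 at 30 °C and -0.81 at 8 °C.

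The other 8 had a value above 0. Acot2, a mitochondrial thioesterase, stood at 1.58 (SE 0.21, adjusted p = 0.0267), from -0.05 at 30 °C and 1.53 at 8 °C. For Kng1, a kininogen, the value was 1.56 (SE 0.19, adjusted p = 0.0267), with 0.13 at 30 °C and 1.69 at 8 °C. Hcn2 had 1.32 (SE 0.20, adjusted p = 0.0336), from -0.10 at 30 °C and 1.23 at 8 °C. Mreg stood at 1.31 (SE 0.19, adjusted p = 0.0270), from -0.56 at 30 °C and 0.76 at 8 °C. For Perm1 the value was 1.20 (SE 0.19, adjusted p = 0.0336), with -0.10 at 30 °C and 1.10 at 8 °C. Mrgbp had 1.02 (SE 0.16, adjusted p = 0.0336), from -0.53 at 30 °C and 0.49 at 8 °C. Sat1, of polyamine breakdown, stood at 0.98 (SE 0.15, adjusted p = 0.0336), from -0.14 at 30 °C and 0.84 at 8 °C. For Wars, a tRNA synthetase, the value was 0.68 (SE 0.11, adjusted p = 0.0336), with -0.08 at 30 °C and 0.59 at 8 °C.

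Of 100 drawn splits of the 6 libraries at each temperature, 3 gave at least the 15 genes of the real split, the real one included, and the highest other gave 319. That share is under 0.05, but with an unexplained split at 140 chance was not excluded. The split with 319 exchanges the genotypes at one temperature only, so that its contrast is the sum of both genotype effects, a structure of the samples. The next, with 140, is that split with WT_8C replicate 2 exchanged for AKO_8C replicate 3, but 3 other such exchanges gave 1, 1 and 4, so its count is unexplained. The count fell to between 0 and 2 when any library at 30 °C was left out, or AKO_8C replicate 1 or 3.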

How the results depend on the processing

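The alternatives with another pseudocount, filter at 5 FPKM, scaling or no variance trend were tests chosen after the values were seen. Both cold responses kept their size, at 5226 to 6441 genes in WT and 5508 to 6126 in AKO with 1 library left out, and the genotype counts did not. Unless stated, the cause of a moved value was not tested. Planned tests for counts (edgeR, DESeq2 and voom, with their normalizations and dispersion options) were not run, as the table holds FPKM.

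AKO against WT at 30 °C, with 105 genes, gave 1 with no filter, 49 with a robust variance, 65 with median ratio scaling, 69 with no variance trend, and 0 to 29 with 1 library left out. At 8 °C, with 268, it gave 172 with no filter, 6 in a fit of the 6 libraries alone, 178 with equal-sum scaling, 44 with an absolute log2 fold change of at least 1, which removes smaller changes by construction, and 23 to 196 with 1 library left out. That minimum left 1253 genes for cold in WT and 1596 in AKO. The interaction, with 15 genes, gave 1 with no filter, 4 with a pseudocount of 0.1, 9 with median ratio scaling, 8 with equal-sum scaling, and 0 to 17 with 1 library left out. The overlap of 3 genes was 0 with no filter and 0 in fits of 6 libraries (381 and 323 in both at an unadjusted p under 0.05 in limma), 1 with equal-sum scaling, 21 at an adjusted p of 0.10, which admits more genes by construction, and 0 to 8 with 1 library left out. Of the authors' 8 °C genes, 180 passed, against 105 with no filter, 4 in the fit of 6 libraries and 20 to 131 with 1 library left out. Of their 30 °C genes, 102 passed, against 1 with no filter, 48 with a robust variance, 63 with median ratio scaling and 0 to 28 with 1 library left out.

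With the replicate number as a block, 30 °C gave 1 gene, 8 °C 419, the interaction 23, the overlap 0 (416 in both at an unadjusted p under 0.05 in limma) and 1 of the authors' 30 °C genes. The samples were taken to share only a number, as 8 of 18 same-numbered correlations exceeded 0.1 (-0.109 to 0.205). All 3 did so for AKO_30C with WT_8C (0.205, 0.148 and 0.116), groups that no comparison sets against each other, and for no other 2 groups. A library correlated best with its own number in 17 of 36 cases.

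With an estimated correlation camera called 0 lists for 30 °C, 1 for 8 °C, 0 for cold in WT, 0 for cold in AKO and 1 for the interaction, and fry 3, 2, 19, 14 and 1, against 14, 13, 14, 15 and 19 as reported. The adjusted p with an estimated correlation was at least 0.181 at 30 °C, 0.366 for cold in WT and 0.127 for cold in AKO.

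Among 126 called values of named genes, the call was lost for 48 with no filter, 29 of 112 in fits of 6 libraries, 20 with a pseudocount of 0.1, 21 with equal-sum scaling, 14 with median ratio, 10 with upper quartile scaling, and for 335 of 840 with 1 library left out, and 0 were reversed in sign. Genes that did not pass changed sign. Under median ratio scaling Cidea at 30 °C was 0.00237 and Sec61a1 at 8 °C -0.0126. Under upper quartile scaling Cidea and Hspa5 at 30 °C were 0.0362 and 0.00925, Sec61a1 -0.0332 at 8 °C, -0.0605 for cold in AKO and -0.0217 in the interaction, and Ern1 -0.0143 in the interaction. Under equal-sum scaling Cidea and Hspa5 at 30 °C were 0.0415 and 0.0145, Sec61a1 at 8 °C -0.0467, Bloc1s1, Prdm16 and Sec61a1 for cold in AKO -0.0646, -0.0189 and -0.21, and Ern1 and Sec61a1 in the interaction -0.0373 and -0.0403. With 1 library left out, values of genes that did not pass crossed 0. In AKO against WT at 30 °C, these ran from -0.0451 to 0.20 for Adrb3, -0.55 to 0.41 for Cidea, -0.32 to 0.0756 for Dio2, -0.12 to 0.00567 for Elovl3, -0.11 to 0.0151 for Hspa5, -0.18 to 0.16 for Ppargc1a, -0.12 to 0.0235 for Sec61a1 and -0.64 to 0.81 for Ucp1. In AKO against WT at 8 °C, these ran from -0.43 to 0.0419 for Fasn, -0.0365 to 0.16 for Prdm16 and -0.0699 to 0.0728 for Sec61a1. In cold in WT, these ran from -0.16 to 0.0128 for Ddit3 and -0.0866 to 0.0594 for Sec61a1. In cold in AKO, these ran from -0.00119 to 0.35 for Prdm16, -0.0341 to 0.11 for Sec61a1 and -0.38 to 0.19 for Xbp1. In the interaction, these ran from -0.0192 to 0.15 for Ern1, -0.0123 to 0.14 for Sec61a1, -0.18 to 1.28 for Ucp1 and -0.0814 to 0.50 for Xbp1. Depth is unknown, so its limit on low genes could not be assessed.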

Other observations

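The gene families and the tests on them were chosen after the result was seen, as were the tests of adipocyte share, single libraries, scaling, wrong label, strain segment, pseudogene reads and dilution below, while the tests of muscle, lymph node and sample splits were planned before. Enzymes that charge tRNAs with amino acids in the cytosol were higher in AKO at 8 °C, 7 of 20 over all genes tested against 186 of 13195 other genes (two-sided Fisher's exact p = 8.39e-09), at log2 fold changes of 0.68 for Eprs, 0.60 for Gars, 0.59 for Wars, 0.54 for Nars, 0.54 for Yars, 0.44 for Cars and 0.33 for Sars. The median of the 20 was 0.30 and above 0 under each scaling, with 5 higher under each of the 3 others, and with 1 library left out 4, 3 and 2 were higher without WT_8C replicates 1, 2 and 3 and 3, 4 and 2 without AKO_8C replicates 1, 2 and 3. Of 17 mitochondrial tRNA synthetases limma called 0, with 2 higher at an unadjusted p under 0.05. Acyl-CoA thioesterases, which release fatty acids from coenzyme A, were higher in 5 of 11 (two-sided Fisher's exact p = 2.71e-07), at 1.53 for Acot2, 0.94 for Acot1, 0.93 for Acot4, 0.88 for Acot5 and 0.73 for Acot12, with 4, 3 and 2 higher after median ratio, upper quartile and equal-sum scaling and 1 or 2 with any 1 library left out. Parts of the mitochondrial protein import machinery were higher in 5 of 29 (two-sided Fisher's exact p = 5.63e-05), at 0.67 for Hspa9, 0.55 for Timm10, 0.52 for Samm50, 0.48 for Chchd4 and 0.47 for Timm17a, with 3 without AKO_8C replicate 1, 1 without AKO_8C replicate 2 or any WT_8C library and 0 without AKO_8C replicate 3 (15 at an unadjusted p under 0.05). These p treat genes as independent, and the families were picked from called genes, so they are not independent evidence. At 30 °C limma called 0 of these genes, with 1 cytosolic and 2 mitochondrial synthetases lower at an unadjusted p under 0.05.

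Fibroblast, matrix, macrophage and mast cell genes lay higher in AKO at 30 °C, list calls that were lost with an estimated correlation (adjusted p = 0.181 to 0.195). Less adipocyte RNA would raise all other markers alike. The fibroblast lower quartile, 0.675, lay 1.11 above the T cell upper quartile, -0.432, but T cells, already seen lower, cannot decide this. With 1 library left out the fibroblast median was 0.874 at the lowest and 1.27 at the highest, against 1.14, so no 1 library of the 6 carried it, and it stayed at least 1.19 above the median of all genes under 4 scalings. The genotype, or less adipocyte RNA or more stroma in the AKO_30C pieces for another reason, may explain it, and these were not separated.

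Zfp949, on chromosome 9, 88548020 to 88571061 (GRCm38), and Morf4l1-ps1, on chromosome 16, 24529394 to 24530362 (GRCm38), were high in 5 of the 6 AKO libraries and low in AKO_30C replicate 3 and all WT libraries. If a mislabelled WT sample, AKO_30C replicate 3 would lie at 0 on a scale where replicates 1 and 2 define 1. Its median was 1.59 over 111 genes (quartiles 1.25 and 1.74). Over 60 also differing at 8 °C, added after the first was seen, it was 0.905 (quartiles 0.444 and 1.37). Both lay nearer AKO, but its Ern1, 3.45 FPKM, lay nearer WT_30C (up to 3.32). A rule set after both were seen left a wrong label open, as the second lower quartile is under 0.5. A strain segment could not be excluded either, since 7 of 21 genes within 2 Mb of Zfp949 had an unadjusted p under 0.05 at 8 °C (two-sided Fisher's exact p = 0.160). A fixed share of Morf4l1 reads in its pseudogene would move both, but Morf4l1 differed by -0.0434 (SE 0.0922). A share that varies and biological explanations were not tested.

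Skeletal muscle and lymphocyte markers were lower at 8 °C in both genotypes. More adipocyte RNA diluting all other types would lower the markers alike, but the lower quartile of the endothelium list lay above the upper quartile of the muscle list, by 1.80 in WT and 2.47 in AKO. Within a group, muscle markers varied together at a mean correlation of 0.749, against at most 0.359 in 1000 random lists. B cell markers did at 0.901 against 0.308. No other cell type was compared, so unequal amounts of muscle or lymph node in the pieces stayed open, as did dilution and an effect of temperature.

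Splits of 3 against 3 number 10, too few for a share under 0.05. The real split called 105, 268, 6479 and 6548 genes for AKO against WT at 30 °C, AKO against WT at 8 °C, cold in WT and cold in AKO, and the highest other 6, 11, 0 and 1, so 1 split of 10, the real one, gave as many in each. For gene lists the real split called 14, 13, 14 and 15 and the highest other 18, 21, 19 and 17, with 6, 7, 10 and 6 of 10 splits giving as many. For the interaction 6 of 100 drawn splits gave at least the 19 lists of the real one, and the highest other gave 21, so chance could not be excluded for that number of lists at the preset correlation.

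Some values are uncertain. Eif3j1 and Eif3j2 ranged over the libraries from 0.0863 to 21.9 and 0.367 to 40.9 FPKM, and Amd1 and Amd2 from 0.0161 to 28.8 and 0.294 to 23.1 FPKM. In each pair of similar genes one was near 0 in several libraries where the other was high.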
